A study of Mus musculus with 79 samples.

How the data were processed

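RNA sequencing of mouse embryonic stem cells was analysed in 3 sets of libraries: total RNA of wild-type E14 cells, nuclear RNA of SCC1-mAID cells and nuclear RNA of clones with a deletion in the Hoxb locus, with 25, 12 and 42 libraries. Per the submitters' protocols, ribosomal RNA was depleted, directional libraries were sequenced as paired reads, and cells of the Drosophila line SG4 were mixed in for calibration. Per the submitters' processing notes, STAR, Bowtie2, SAMtools and DESeq2 were used with the genome builds mm10 and dm6; no versions, parameters or order of steps are stated, nor is the program that counted reads. The deposited tables hold a normalised signal for each RefSeq transcript and library.

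In the deposited tables, each library's signal is the read count divided by a single size factor. Each column consists of multiples of a common step, so whole reads were recovered as signal times size factor; at least 99.997% of values in each library lay within 0.1 read of a whole number. Transcripts of the same span had equal signals in 3096 of 3096 sets in the SCC1-mAID table and in 3460 of 3460 sets in the clone table, so these tables count reads over the whole span, introns included. In the E14 table this held for 349 of 3251 sets (10.7%), and its reads are exonic. The authors also deposited FPKM for E14 libraries; it was used only to look at the length it was divided by. The authors' log2 fold change between groups, made with DESeq2, was not used in the comparisons. The authors' adjusted p-value, deposited beside it, served only for the counts of their calls per transcript. Whether the authors' size factors in the E14 and SCC1-mAID tables came from the Drosophila reads is not stated. They differ from DESeq2's median-of-ratios factors computed on the same reads, with ratios from 0.804 to 1.139 in E14 and from 0.638 to 2.15 in SCC1-mAID, against 0.999 to 1.0 in the clones.

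The tables hold 29076, 35326 and 29039 transcripts for E14, SCC1-mAID and the clones. In the SCC1-mAID table, which pairs no symbols with its identifiers, 29076 transcripts were named from the other tables, 5291 from a RefSeq table and 959 could not be named. A single transcript per gene symbol was kept, the one with the highest mean share of reads, leaving 19526, 21193 and 19482 genes with reads. Coordinates are those of the authors' files, build mm10 per the labels, counted from 1. Where a transcript lay inside a transcript of the other strand, it had more reads than the one around it in 145 of 406 cases (35.7%) in E14 and in 58 of 435 cases (13.3%) in the clones; the tables do not state whether counting used the strand.

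Recovered reads were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3 (statmod 1.5.0). Each set was fitted on its own with a mean per group, TMM scaling, genes kept by filterByExpr, robust quasi-likelihood tests and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, and calls of at least 2-fold were counted beside all calls. After filtering, 15084 genes were tested in E14, 14031 in SCC1-mAID and 15923 in the clones, holding 99.90%, 99.77% and 99.93% of reads. Changes are given as log2 fold change ± an approximate standard error (SE). This SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F. It is unreliable for changes near 0 and for groups with few or no reads. Levels are given as edgeR's CPM, reads scaled to TMM library size, ± SD over libraries. Comparisons were each time of retinoic acid against 0 h in E14; the 4 treatment contrasts and their interaction in SCC1-mAID; and, in the clones, the mean of the deletion clones E3 and H12 against the wild-type clone G4, E3 against H12, each deletion clone against G4, and the difference between deletion and wild-type clones in the response to retinoic acid. The untreated E14 group has 2 libraries and each clone has 2 libraries per time, so all groups of a set share the estimate of spread.

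An E14 gene was classed as transient-up when it was called up at least 2-fold at 2, 4 or 6 h, called down at 72 h against the early time with its highest fold, and under 2-fold above 0 h at 72 h. Early-sustained genes were called up at least 2-fold early and at 72 h; late genes only at 72 h. The comparisons, classes, gene lists, choice of named genes and alternatives were fixed before the data were examined, except those said to be chosen later.

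Lists covered the retinoic acid pathway, Hoxa, Hoxb, Hoxc and Hoxd genes, neighbours of Hoxb, other homeobox partners, naive pluripotency, general pluripotency, formative and primed pluripotency, neural progenitors, extra-embryonic endoderm, primitive streak and mesoderm, trophoblast, 2-cell-like cells, fibroblasts, cohesin and CTCF, p53 targets, immediate early genes, aryl hydrocarbon receptor targets, mitochondrially encoded genes, apoptosis and stress, and nuclear long noncoding RNAs. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison; fry was run beside it. Genes were named by rule: every Hoxb gene in E14 and the clones and Rad21 in SCC1-mAID; up to 4 called and 2 uncalled members of each other list; and the 6 largest rises and falls with at least 1 CPM in the higher group and no overlap between the groups' libraries, or the 3 largest for the deletion clones if alike in both clones. Not every gene the rule allows is printed.

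The steps were tested on simulated counts, drawn from each gene's mean and spread in the recovered reads, with known changes added. Genes were drawn independently and libraries differed only in depth. The rates therefore do not cover further structure among the real libraries. For E14 at 2 h (14302 genes), 73% of 100 genes changed 2-fold and 91% of 100 changed 4-fold were called, with 5.2% false calls. For retinoic acid against untreated SCC1-mAID cells (13871 genes) the figures were 75%, 97% and 6.5%, and for deletion against wild-type clones at 0 h (15392 genes) 73%, 87% and 3.6%.

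Replicate numbers were checked for pairing by correlating, across genes, the deviations of libraries with the same number. For retinoic acid against untreated SCC1-mAID cells the 3 values of r were 0.19, 0.27 and 0.26, and a fit with the replicate number as a block called 457 genes beside 361 without it. Alternatives tried were edgeR's RLE factors, the authors' scaling kept as it is, no filter on low counts, DESeq2 1.42.0, limma with trend on log CPM, the replicate block, a fit of the compared groups alone, 2-fold calls, a 1.5-fold class limit, each clone alone and leaving out each library. limma on log2 of the deposited value plus 1 was added after seeing the data. Recovery, tables and plots used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. One SCC1-mAID replicate of each treatment is numbered 3 in its title and 4 in its description; titles were used. The deleted interval is not given in the labels, so its reads were not examined.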

Results

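RNA was measured in 79 libraries of mouse embryonic stem cells exposed to 1 uM retinoic acid (RA), a signal that makes these cells differentiate. The first set is total RNA of wild-type E14 cells, with 2 libraries at 0 h, 4 each at 2, 4, 6, 48 and 72 h, and 3 at 24 h. The second is nuclear RNA of SCC1-mAID cells, in which the cohesin subunit SCC1 (gene Rad21) carries a tag that lets auxin destroy the protein. It holds 3 libraries each of untreated cells, cells with RA for 4 h, cells with 500 uM auxin for 6 h, and cells with auxin for 6 h and RA for the last 4 h. The third is nuclear RNA of clones made to delete a transient enhancer in the Hoxb locus: deletion clones E3 and H12 and a wild-type clone, G4. Each clone has 2 libraries at each of 7 times, from 0 h to 74 h of RA. The last E14 time is 72 h in the titles and 74 h in the sample characteristics. Recovered reads per library numbered 2352114 to 21082331 in E14, 3126363 to 7499040 in SCC1-mAID and 4754309 to 10450047 in the clones. The E14 0 h libraries were the deepest of their set, at 16236549 and 21082331, and those from 24 h on held 2352114 to 4123211.

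The E14 time course asks which genes respond to RA and when. Within 2 h, genes that degrade or sense RA rose. Cyp26a1, which encodes an RA hydroxylase (mm10 chromosome 19, 37697808 to 37701536), rose from 16 ± 3.16 CPM (SD, n = 2) to 148 ± 36.3 CPM (n = 4; 3.20 ± 0.35, adjusted p = 2.79e-05). The RA target Stra8 (chromosome 6, 34920960 to 34939342) rose by 2.59 ± 0.25, adjusted p = 2.86e-06, the retinal reductase Dhrs3 (chromosome 4, 144893137 to 144927645) by 2.03 ± 0.22, adjusted p = 6.53e-06, and the nuclear receptor corepressor Nrip1 (chromosome 16, 76290862 to 76373049) by 1.79 ± 0.23, adjusted p = 1.05e-04. Hox genes started to rise with Hoxb4 (chromosome 11, 96318267 to 96321638; 3.30 ± 0.51, adjusted p = 5.88e-04), Hoxa3 (3.20 ± 0.47) and Hoxa5 (2.37 ± 0.49). Foxd3, a transcription factor of pluripotent cells, fell (-1.58 ± 0.21, adjusted p = 7.50e-05), as did Socs3, a feedback inhibitor of cytokine signalling (-1.17 ± 0.16), the transcription factor Bcl11a (-2.03 ± 0.42) and the cytokine Tnfsf11 (-1.36 ± 0.21). In all, 61 genes rose and 14 fell of 15084 tested, 42 and 6 of them at least 2-fold. Other large rises were those of the sperm protein gene Zan (3.01 ± 0.33), the zinc finger gene Zfp703 (2.48 ± 0.53) and the endoderm factor Gata6 (1.76 ± 0.33).

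By list, 7 of 18 retinoic acid pathway genes had risen at 2 h and none had fallen (9 adjusted over the list alone; camera adjusted p = 9.30e-30, or 3.78e-06 with an estimated correlation). Of the Hoxa genes 3 of 9 were called (4 adjusted over the list alone; adjusted p = 3.78e-06 with an estimated correlation), and of the Hoxb genes 1 of 10 (5; 0.00894). Camera also called the homeobox partners, p53 targets, fibroblast genes and aryl hydrocarbon receptor targets as higher. These lists had 0 members called, and with an estimated correlation their adjusted p values were 0.0835, 0.0754, 0.563 and 0.0516. Fry, which asks whether a list's genes move on balance in a single direction and does not compare them with other genes, gave adjusted p = 3.65e-07 for the pathway list. Without either of the 0 h libraries the count of called genes at 2 h was 18 or 20, so the early counts rest on both. DESeq2 called 140 genes at 2 h, limma-trend 43 and limma on the deposited value 40. The 0 h libraries are replicates 3 and 4, while the groups at 2, 4 and 6 h also hold replicates 1 and 2. At 2 h the chi-squared per gene between replicates 3 and 4 was 2.35, against 11.96 to 17.13 for other pairs. At 4 h it was 2.93 against 10.86 to 21.92, and at 6 h 13.83 against 6.72 to 17.15. The early contrasts with 0 h may therefore partly reflect which replicates each group holds. With the replicate number as a block the counts did not fall: 128, 552 and 879 genes were called at 2, 4 and 6 h, against 75, 368 and 597 without it. The block does not settle the point, since the numbers do not pair the libraries throughout.

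At 4 h the same pathway genes were higher still, and further Hoxb genes joined them. Cyp26a1 stood 4.15 ± 0.37, adjusted p = 6.61e-07 above 0 h, Stra8 3.57 ± 0.26, Dhrs3 2.48 ± 0.22, Nrip1 2.21 ± 0.24 and another RA hydroxylase gene, Cyp26b1 (chromosome 6, 84571414 to 84593810), 4.19 ± 0.75. Hoxb1 rose by 3.39 ± 0.82, adjusted p = 0.028, Hoxb2 by 4.18 ± 0.92, Hoxb3 by 3.23 ± 0.77 and Hoxb4 by 4.08 ± 0.49. The fitted changes of Hoxb5 and Hoxb6 were of like size, at 3.62 and 4.83, so the rise was not limited to the anterior genes. The Hox cofactors Meis2 (1.88 ± 0.45) and Pbx2 (0.74 ± 0.17), the caudal homeobox gene Cdx1 (3.66 ± 0.88) and the endoderm factor Gata6 (2.25 ± 0.33) rose too. Foxd3 (-1.81 ± 0.21, adjusted p = 3.29e-06), the Wnt effector Lef1 (-1.22 ± 0.20) and the cadherin Cdh9 (-1.73 ± 0.36) fell. 231 genes rose and 137 fell, 129 and 63 at least 2-fold. The called members were 9 of 18 pathway genes (9 adjusted over the list alone), 5 of 9 Hoxa (6), 5 of 10 Hoxb (8) and 3 of 8 homeobox partners (3), and all of these lists were called by camera with an estimated correlation, the Hoxb list at adjusted p = 0.00255 and the partners at 0.0175. Among formative and primed pluripotency genes Sox3 rose (0.94 ± 0.24) and Lef1 fell; the list's camera adjusted p was 0.0453, and 0.0736 with an estimated correlation. The count of called genes was 70 and 83 without 0 h replicates 3 and 4, 164 with limma-trend and 134 with limma on the deposited value.

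At 6 h, 326 genes rose and 271 fell, 188 and 122 at least 2-fold; under the authors' scaling the split was 247 up and 391 down. Cyp26a1 reached 4.44 ± 0.38, Stra8 3.97 ± 0.26, the retinol receptor gene Stra6 3.52 ± 0.34, adjusted p = 7.50e-07 and Cyp26b1 4.89 ± 0.75. In the Hoxb cluster Hoxb1 (3.97 ± 0.79), Hoxb2 (4.51 ± 0.90), Hoxb3 (4.11 ± 0.72), Hoxb4 (4.66 ± 0.48, adjusted p = 4.62e-07) and the distant Hoxb13 (1.75 ± 0.50) had risen, and 7 of 10 Hoxb genes were called (9 adjusted over the list alone; adjusted p = 0.00112 with an estimated correlation). Hoxb5 and Hoxb6 stood 4.71 and 5.43 above 0 h. Factors of the state after the naive one fell: Otx2 (-2.29 ± 0.57), Fgf5 (-1.55 ± 0.34) and the DNA methyltransferase gene Dnmt3b (-0.66 ± 0.17). The formative and primed list had 1 member up and 4 down of 11 (2 and 6 adjusted over the list alone; camera adjusted p = 0.0287, or 0.0525 with an estimated correlation). The imprinted noncoding RNA Meg3 (-0.90 ± 0.23), Ly6g6e (-2.53 ± 0.40) and the kallikrein gene Klk1 (-2.36 ± 0.38) fell as well. Without 0 h replicates 3 and 4 the counts of called genes were 148 and 172, and limma-trend called 321.

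By 24 h all 10 measured Hoxb and all 9 measured Hoxa genes had risen. Hoxb1 stood at 43.9 ± 25.1 CPM (n = 3) against 0.331 ± 0.0633 CPM at 0 h (6.98 ± 0.75, adjusted p = 1.83e-06), and Hoxb2 (8.19 ± 0.75), Hoxb3 (6.60 ± 0.67), Hoxb4 (6.35 ± 0.48) and Hoxb9 (3.02 ± 0.37) followed it. Stra8 peaked at this time (5.80 ± 0.29), Meis1 (3.44 ± 0.42), Meis2 (4.08 ± 0.48) and Cdx1 (5.46 ± 0.94) rose, and so did the neural and endodermal factors Msx1 (3.54 ± 0.44) and Foxa2 (3.75 ± 0.64). Further genes of pluripotent cells were lower: Fgf4 (-1.89 ± 0.28, adjusted p = 4.57e-05), Nr5a2 (-1.25 ± 0.22), Nr0b1 (-1.11 ± 0.37), Utf1 (-0.95 ± 0.27) and Dnmt3b (-1.53 ± 0.19), together with the lysophospholipase gene Enpp2 (-4.36 ± 0.33). 2124 genes rose and 2006 fell, with 2244 and 1916 called without 0 h replicates 3 and 4. Called up were 11 of 18 pathway genes, 7 of 8 homeobox partners and 6 of 12 Hoxc and Hoxd genes (11 adjusted over the list alone; camera adjusted p = 0.00159, or 0.128 with an estimated correlation). Of 16 naive pluripotency genes 4 fell, and camera's call (0.0341) was lost with an estimated correlation (adjusted p = 0.723). The same held for extra-embryonic endoderm (0.0158; 0.621) and 2-cell-like genes (0.00833; 0.687), with 7 of 20 and 7 of 13 members up.

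At 48 h, 4352 genes rose and 4054 fell. Hoxb2 reached 9.32 ± 0.73, adjusted p = 2.84e-09, Hoxb1 7.99 ± 0.74 and Hoxb4 6.94 ± 0.47, the highest values of the course for these genes. Fgf4 (-3.73 ± 0.27), Gdf3 (-2.02 ± 0.19), L1td1 (-2.54 ± 0.32) and Utf1 (-2.77 ± 0.27), all of pluripotent cells, were lower, and Lrrc2 fell (-5.84 ± 0.31). Zscan4c (5.10 ± 0.43) and Zscan4d (5.46 ± 0.46), which mark a state like the 2-cell embryo, rose along with all 13 measured genes of that list (camera adjusted p = 1.57e-09, or 0.0632 with an estimated correlation). The immediate early genes Fos (3.13 ± 0.36), Egr1 (2.27 ± 0.34) and Jun (2.82 ± 0.41) rose, 8 of 14 in that list. The aryl hydrocarbon receptor targets split, with Cyp1b1 up (4.17 ± 0.72) and Cyp1a1 down (-4.09 ± 0.69). Neural progenitor genes had 11 up and 2 down of 22 (camera adjusted p = 0.0607), with Zic1 (4.18 ± 0.60) and Irx3 (3.79 ± 0.47) up and Neurod1 down (-3.40 ± 0.42). Extra-embryonic endoderm had 14 of 20 up (adjusted p = 0.105 with an estimated correlation), and naive and general pluripotency 9 of 16 and 9 of 13 down (0.5 and 0.355).

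At 72 h most tested genes were called, 4587 up and 4423 down. The authors' scaling moved the median of all genes at this time by 0.27 and gave 5887 up and 2800 down. Endoderm factors were far above 0 h, as Gata6 (5.09 ± 0.34, adjusted p = 5.68e-12), Gata4 (3.92 ± 0.40), Sox17 (5.87 ± 0.54) and Pdgfra (4.67 ± 0.35), and so were neural and mesenchymal factors, as Zic1 (6.33 ± 0.57), Irx3 (4.94 ± 0.47), Msx1 (5.78 ± 0.44), Meox1 (4.54 ± 0.42) and Twist1 (4.79 ± 0.37). The TGF-beta ligand gene Gdf3 fell from 273 ± 7.07 to 20.1 ± 6.46 CPM (-3.74 ± 0.21, adjusted p = 5.07e-13), with Fgf4 (-4.22 ± 0.28), Nr0b1 (-3.46 ± 0.42), Klf2 (-2.22 ± 0.23), Pou3f1 (-3.23 ± 0.30), Dnmt3b (-2.29 ± 0.17) and Neurod1 (-4.09 ± 0.46). Nanog was not called (-0.33 ± 0.44, adjusted p = 0.537). The RA pathway had 14 of 18 up and 1 down, and all 9 Hoxa, 10 Hoxb and 12 Hoxc and Hoxd genes were up. General pluripotency had 12 of 13 down, naive pluripotency 12 of 16, and formative and primed genes 3 up and 6 down of 11. Of neural progenitor genes 14 of 22 were up, of extra-embryonic endoderm 16 of 20, of 2-cell-like genes 13 of 13, of fibroblast genes 8 of 11, of trophoblast genes 6 of 9 and of homeobox partners 7 of 8. With an estimated correlation camera's adjusted p was 0.0388 for extra-embryonic endoderm, 0.0882 for 2-cell-like, 0.125 for general pluripotency, 0.331 for neural, 0.37 for fibroblast and 0.395 for naive genes.

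Of the remaining lists at 72 h, neighbours of Hoxb had 4 up and 10 down of 26, cohesin and CTCF genes 4 and 4 of 16, p53 targets 2 and 7 of 15, and aryl hydrocarbon receptor targets 2 and 4 of 8. Primitive streak and mesoderm genes had 3 up and 0 down of 12, immediate early genes 5 and 3 of 14, apoptosis and stress genes 5 and 2 of 13, and nuclear long noncoding RNAs 0 and 0 of 8. Of mitochondrially encoded genes 0 were measured. The median of the Hoxb neighbours was -0.17, against 0.08 under the authors' scaling, and that of the primitive streak list -0.20 against 0.05, so both change sign. Among the neighbours, B4galnt2 (2.60 ± 0.37) and Copz2 (3.20 ± 0.43) rose and Atp5g1 (-1.25 ± 0.20) and Snx11 (-1.08 ± 0.15) fell. Among cohesin genes Cdca5 (-0.98 ± 0.12) and Esco2 (-1.12 ± 0.15) fell and Stag2 rose (0.59 ± 0.13).

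A group of 79 genes rose early and came back (28 and 29 genes without 0 h replicates 3 and 4, and 44 by limma-trend): they were up at least 2-fold at 2, 4 or 6 h, lower again at 72 h than at their peak, and under 2-fold above 0 h by then. The peak here is the highest fold among 2, 4 and 6 h only. It lay at 2 h in 4 genes, at 4 h in 21 and at 6 h in 54. Times between 6 and 72 h were not used for the class, so members may have risen further after 6 h. Zan rose the most, at 3.01, 4.06 and 4.13 at 2, 4 and 6 h and -0.48 at 72 h. Nt5e, a nucleotidase, stood at 1.96, 2.36, 2.51 and 0.32. Tmtc1, a mannosyltransferase gene, was at 1.57, 2.20, 2.48 and -0.48, and the kinase gene Srms at 2.08 at 6 h and -0.37 at 72 h. The last 3 genes were chosen after their values were seen. The class has no lower limit at 72 h, where its members ran from -4.67 (Cdk15) to 0.98 (Cldn19). Membership therefore does not mean a return to the 0 h level, and some members ended well below it. None of the 79 belongs to a fixed list. A further 108 genes rose early and stayed up, among them Cyp26a1, Cyp26b1, Stra8, Stra6, Cdx1 and the anterior Hoxb genes, 2613 rose late, and 8 rose early and fit neither class. The authors' own class of transient induction covers 104 transcripts of 75 genes; 46 of the 79 genes carry it, as does Cyp26a1, which was still 2.75 above 0 h at 72 h.

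**Figure D1:**
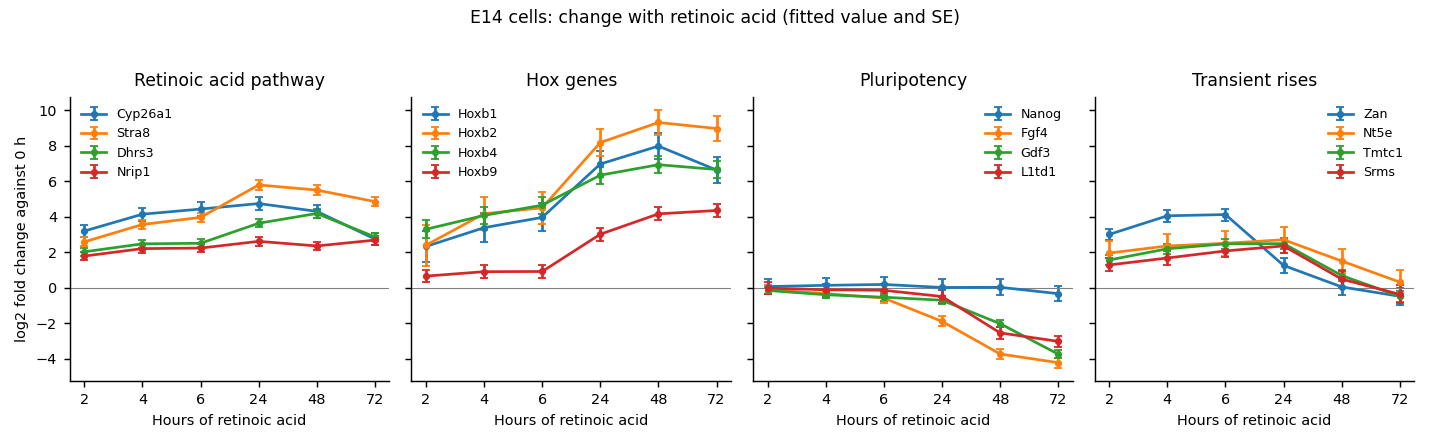
Log2 fold change against 0 h (fitted value, bars SE) of 16 genes in E14 cells over hours of retinoic acid (evenly spaced, not to scale), in 4 panels. Hoxb2 climbs to 9.32 at 48 h, Gdf3 falls to -3.74 at 72 h, and Zan passes 4.06 at 4 h and is at -0.48 at 72 h.

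The SCC1-mAID set asks whether the response to RA needs cohesin. Rad21 RNA, from the gene whose protein auxin removes (chromosome 15, 51962604 to 51991760), was not called in any contrast: it stood at 249 ± 9.13 CPM untreated, 256 ± 6.11 with RA, 269 ± 9.96 with auxin and 276 ± 34.7 with both (SD, n = 3 each), and the auxin contrast was 0.11 ± 0.12, adjusted p = 0.771. The tables hold no protein measurement, so depletion itself is not shown by them. Without auxin, 4 h of RA raised Cyp26a1 from 3.06 ± 0.3 to 330 ± 43.8 CPM (6.76 ± 0.28, adjusted p = 1.63e-10). Cyp26b1 (5.23 ± 0.32, adjusted p = 1.92e-08), Stra8 (3.48 ± 0.18), Nrip1 (2.55 ± 0.16), Hoxa3 (3.82 ± 0.51), Hoxb3 (3.41 ± 0.41), Hoxb4 (4.00 ± 0.45), Cdx1 (3.57 ± 0.25), Meis2 (2.11 ± 0.27) and Pbx2 (0.64 ± 0.15) rose. The Wnt ligand gene Wnt8a (1.68 ± 0.22), the stress factors Atf3 (2.51 ± 0.45) and Ddit3 (1.25 ± 0.28), and the Hoxb neighbours Skap1 (1.10 ± 0.27) and Ttll6 (1.31 ± 0.27) rose too. Foxd3 (-1.86 ± 0.18, adjusted p = 5.06e-06), Otx2 (-1.85 ± 0.20), Lef1 (-1.34 ± 0.17), Fgf15 (-1.21 ± 0.20), Klf4 (-0.81 ± 0.19), Klf5 (-0.71 ± 0.14), Sox11 (-1.03 ± 0.18) and Junb (-0.90 ± 0.20) fell.

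In all 260 genes rose and 101 fell with RA alone, 164 and 50 at least 2-fold. The authors' scaling moved the median of all genes by 0.19 and left 72 up and 0 down, while a fit of only the compared groups called 490 up and 272 down. Without untreated libraries 1, 2 and 3 the counts were 221, 223 and 212. Called up were 9 of 17 pathway genes (9 adjusted over the list alone; camera adjusted p = 0.00261 with an estimated correlation), 3 of 4 Hoxb and 3 of 7 homeobox partners (5; 0.0262). Down were 3 of 11 formative and primed genes (6; 0.0262), 1 of 9 neural progenitor genes (3; 0.0262) and 2 of 16 naive pluripotency genes. The naive median was -0.14, against 0.10 under the authors' scaling, and that of general pluripotency -0.16 against 0.04.

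With auxin present, RA again raised pathway and Hox genes. For Hoxb1 the fitted rise was weaker than without auxin (difference of response -2.88 ± 1.08), though this difference was not called. Cyp26a1 went from 1.77 ± 0.398 to 256 ± 99.6 CPM (7.23 ± 0.31, adjusted p = 2.30e-10); Stra8 (3.31 ± 0.18), the RA receptor gene Rarb (2.82 ± 0.28), Dhrs3 (2.31 ± 0.20), Hoxa3 (2.69 ± 0.70), Hoxb1 (3.19 ± 0.49), Hoxb3 (3.01 ± 0.50), Hoxb4 (3.32 ± 0.41), Cdx1 (4.40 ± 0.29) and Pbx2 (0.87 ± 0.15) rose. Cyp26b1 went from 0.511 ± 0.121 to 2.1 ± 0.766 CPM (1.97 ± 0.45) and Nrip1 rose by 1.60 ± 0.16. Meis2 (0.57 ± 0.30), Atf3 (0.80 ± 0.42), Ddit3 (0.40 ± 0.27), Skap1 (0.02 ± 0.26) and Ttll6 (0.50 ± 0.25), each called without auxin, were not called with it; the difference between the responses was not called for any of these genes over all genes. Wnt8a (1.59 ± 0.24), the Nodal antagonist Lefty1 (1.11 ± 0.25) and Nr0b1 (0.81 ± 0.19) rose as well. Otx2 (-1.74 ± 0.20, adjusted p = 3.20e-05), Lef1 (-1.35 ± 0.17), the adaptor gene Dapp1 (-1.79 ± 0.26), Wnt5a (-2.40 ± 0.53), Sox2 (-0.67 ± 0.17) and Klf5 (-0.60 ± 0.15) fell. Of all genes 256 rose and 114 fell, 135 and 62 at least 2-fold, or 42 and 5 under the authors' scaling, which moved the median by -0.14. Pathway genes had 10 of 17 up (11 adjusted over the list alone; adjusted p = 0.0033 with an estimated correlation). Camera called the homeobox partners up (0.00109) and nuclear long noncoding RNAs (0.00109; 0 called, 5 adjusted over the list alone) down, with adjusted p = 0.199 and 0.475 with an estimated correlation. The medians of naive (0.11 against -0.02) and general pluripotency (0.15 against -0.05) change sign with that scaling. This count depends on single libraries: it was 828 without auxin and RA library 2 and 719 without auxin library 1. It was 216 and 225 without auxin and RA libraries 1 and 3, and 215 and 223 without auxin libraries 2 and 3. A fit of only these groups called 144, and another split of the libraries into 3 and 3 called 3417.

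Auxin alone changed 33 genes, 14 up and 19 down (2 and 1 under the authors' scaling). The largest rises were of the xenobiotic oxidases Cyp1a1, from 3.51 ± 1.19 to 186 ± 179 CPM (5.77 ± 0.60, adjusted p = 7.70e-04), and Cyp1b1 (4.44 ± 0.54, adjusted p = 0.00141). The ribosomal protein genes Rpl3 (1.07 ± 0.17) and Rps12 (1.01 ± 0.19) and the membrane protein genes Tmem220 (1.14 ± 0.21) and Tmem191c (1.02 ± 0.20) rose. The pluripotency factor Klf4 fell (-1.11 ± 0.19, adjusted p = 0.0261), as did the growth factor receptor Kdr (-1.95 ± 0.33), Tlr2 (-1.53 ± 0.27), Mfap3l (-1.42 ± 0.22), Adgrg6 (-1.33 ± 0.26), the carbonic anhydrase gene Car2 (-1.21 ± 0.16) and Inhbb (-1.14 ± 0.20). Naive pluripotency genes had a median of -0.39; 1 of 16 was called over all genes and 8 adjusted over the list alone (camera adjusted p = 8.29e-07, or 0.014 with an estimated correlation). Aryl hydrocarbon receptor targets had 2 of 8 up (4.49e-05; 0.231 with an estimated correlation). Camera's calls for formative genes (0.0342; 0.252) and for cohesin and CTCF genes (0.0342; 0.622) were lost in the same way. This count is the least firm of the set: it was 4, 6 and 9 without untreated libraries 1, 2 and 3, and 19 and 68 without auxin libraries 2 and 3. DESeq2 called 186 genes, edgeR without the low-count filter 153, and a fit of only the compared groups 4.

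Cells given RA were also compared with and without auxin, which sets levels and not responses side by side. Cyp26b1 stood at 19.8 ± 2.3 CPM with RA and at 2.1 ± 0.766 CPM with auxin and RA (-3.29 ± 0.26, adjusted p = 3.94e-06), and Nrip1 at 181 ± 13.2 and 90.5 ± 11.3 CPM (adjusted p = 0.00563). Meis2 was lower too (-1.69 ± 0.26, adjusted p = 0.00563), with the kinase gene Ak5 (-2.53 ± 0.43), Ajap1 (-2.22 ± 0.37), the hyaluronan synthase gene Has2 (-2.01 ± 0.37), Zfp703 (-1.71 ± 0.28), Necab1 (-1.71 ± 0.34) and Tfap2c (-0.83 ± 0.16). Cyp1a1 (5.84 ± 0.62), Cyp1b1 (4.52 ± 0.62), Igfbp5 (1.83 ± 0.35), Tmem220 (1.26 ± 0.21), Armcx6 (1.03 ± 0.21) and Cc2d2a (0.89 ± 0.14) were higher. Of all genes 6 were higher and 45 lower, 5 and 26 at least 2-fold; the authors' scaling, which moved the median by -0.36, gave 2 and 2. Of 17 pathway genes 2 were lower. Naive pluripotency had 0 called (5 adjusted over the list alone; camera 8.88e-04, or 0.104 with an estimated correlation), and the receptor targets and 2-cell-like lists lost camera's call likewise (0.198 and 0.893). The count of 51 was 8 without auxin and RA library 1, and 24, 30 and 20 without RA libraries 1, 2 and 3. DESeq2 called 96 genes and edgeR without the low-count filter 87.

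The interaction asks directly whether RA acted differently with auxin. edgeR called 0 of 14031 genes, with 974 at an unadjusted p under 0.05; DESeq2 called 5 and limma-trend 1. Among the 214 genes changed at least 2-fold by RA alone, a set chosen on the same libraries and so in favour of a weaker response with auxin, 151 had a weaker response with auxin and 3 were called adjusted over the list alone. These were Ak5 (-3.28 ± 0.69, adjusted p = 0.0255 in that set), Cyp26b1 (-3.27 ± 0.71, 0.0255) and Nrip1 (-0.95 ± 0.22, 0.0356). Meis2 (-1.54 ± 0.40, 0.0705) and Hoxb1 (-2.88 ± 1.08, 0.16) were not called. Over all genes the adjusted p values of Ak5, Cyp26b1 and Nrip1 were 0.464, 0.464 and 0.54. Over the 217 genes of the fixed lists 0 were called, the smallest adjusted p being 0.0518. The authors' scaling moved the median of the interaction by -0.33.

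**Figure D2:**
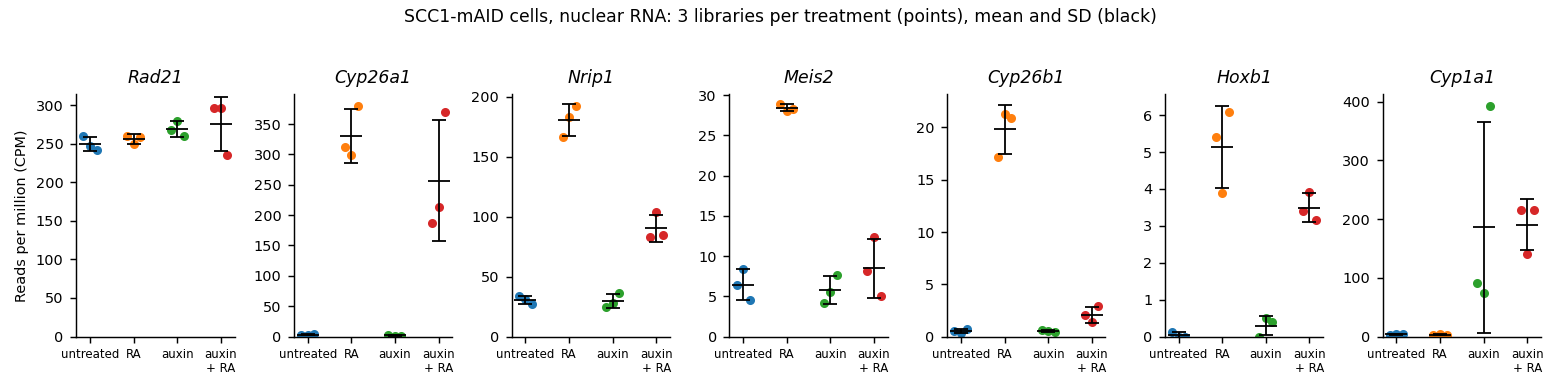
CPM (linear axis) of 7 genes in SCC1-mAID cells, with a point per library, 3 per treatment, and bars for mean and SD. Cyp26b1 reaches 19.8 with RA and 2.1 with auxin and RA, while Rad21 stays between means of 249 and 276.

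The clones ask whether deleting the enhancer in the Hoxb locus changes expression before and during RA. In the wild-type clone 2, 5, 7, 9, 9 and 9 of the 9 measured Hoxb genes had risen at 2, 4, 6, 24, 48 and 74 h. In the deletion clones the cluster was still induced. By the mean of these clones, Hoxb3, Hoxb4 and their neighbours towards Hoxb8 ended lower, but Hoxb3 alone was called in each clone. At 74 h Hoxb3 (chromosome 11, 96323126 to 96347930) stood at 321 ± 45.4 CPM in the wild-type clone, 146 ± 8.06 in E3 and 95.4 ± 7.94 in H12 (SD, n = 2 each; -1.44 ± 0.15, adjusted p = 2.90e-08). Hoxb4 (-0.93 ± 0.19, adjusted p = 0.00103), Hoxb5 (-0.84 ± 0.24), Hoxb6 (-0.76 ± 0.26), Hoxb7 (-0.98 ± 0.32) and Hoxb8 (-0.74 ± 0.21) were lower too, while Hoxb1 (0.20 ± 0.31, adjusted p = 0.724), Hoxb2 (-0.32 ± 0.25) and Hoxb9 (-0.36 ± 0.19) were not called. At 48 h Hoxb3 alone was called (-0.64 ± 0.15, adjusted p = 0.011), and at 24 h it was not (-0.55 ± 0.16, adjusted p = 0.0661). From 0 to 24 h edgeR called 0 Hoxb genes for the mean of the deletion clones, with 0, 0, 3, 1 and 1 at an unadjusted p under 0.05; adjusted over the Hoxb genes and all times alone, 1 was lower at 4 h and 1 at 24 h, with Hoxb3 at -0.76 ± 0.23 at 4 h. Over all times 7 Hoxb calls were made, 3 without either wild-type library or H12 library 1 at 74 h, and 11 without H12 library 2 at 48 h. Limma-trend made 2 Hoxb calls, limma on the deposited value 3 (1 of them higher) and edgeR at 2-fold or more 1. Camera's adjusted p for the list was 0.0299 at 48 h and 0.00679 at 74 h, or 0.171 and 0.0874 with an estimated correlation.

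Per clone at 74 h, 3 Hoxb genes were called lower than wild type in E3 (Hoxb3, Hoxb8 and Hoxb9) and 3 in H12 (Hoxb3, Hoxb4 and Hoxb7). Hoxb5 and Hoxb6 were called in neither clone. Hoxb9 stood at -0.77 (SE 0.22) in E3 and 0.04 (SE 0.22) in H12. Adjusted over the Hoxb genes and all times alone, 6 were lower in E3 and 2 in H12. At 48 h E3 had 2 lower and H12 had 1 higher. E3 was already lower at 24 h in Hoxb3 (-0.93, SE 0.19, adjusted p = 0.0165), with a median of -0.81 over the Hoxb genes and 4 lower when adjusted over these genes and all times alone. In H12 the median at 24 h was 0.14 with 0 called, and 1 gene was higher at 2 h and 1 at 6 h. The deletion clones also differed from each other. At 24 h E3 was called below H12 in 6 of 9 Hoxb genes, among them Hoxb8 (-1.46 ± 0.29, adjusted p = 0.00121), Hoxb5 (-1.17 ± 0.32), Hoxb4 (-0.96 ± 0.25) and Hoxb3 (-0.76 ± 0.19), with a median of -0.94 that exceeds the median of -0.76 between deletion and wild-type clones at 74 h. At 74 h Hoxb3 was higher in E3 than in H12 (0.61 ± 0.18) and Hoxb9 lower (-0.81 ± 0.23). When the response to RA (each time minus 0 h) was compared between deletion and wild-type clones, edgeR called 0 Hoxb genes at any time, over all genes or adjusted over the Hoxb genes and all times alone, with 0, 1, 0, 1, 1 and 1 at an unadjusted p under 0.05 at 2, 4, 6, 24, 48 and 74 h. This test had little power and the 0 is no evidence of equal responses: at 0 h Hoxb2, Hoxb5, Hoxb6, Hoxb7 and Hoxb8 had no reads in at least 1 of the 3 clones, and only Hoxb9 passed 1 CPM. For Hoxb3 the fitted difference at 74 h was -3.28 with an SE of 1.10 (adjusted p = 0.0655). With 2 libraries per clone and a single wild-type clone, the genotype cannot be separated from differences between clones.

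**Figure D3:**
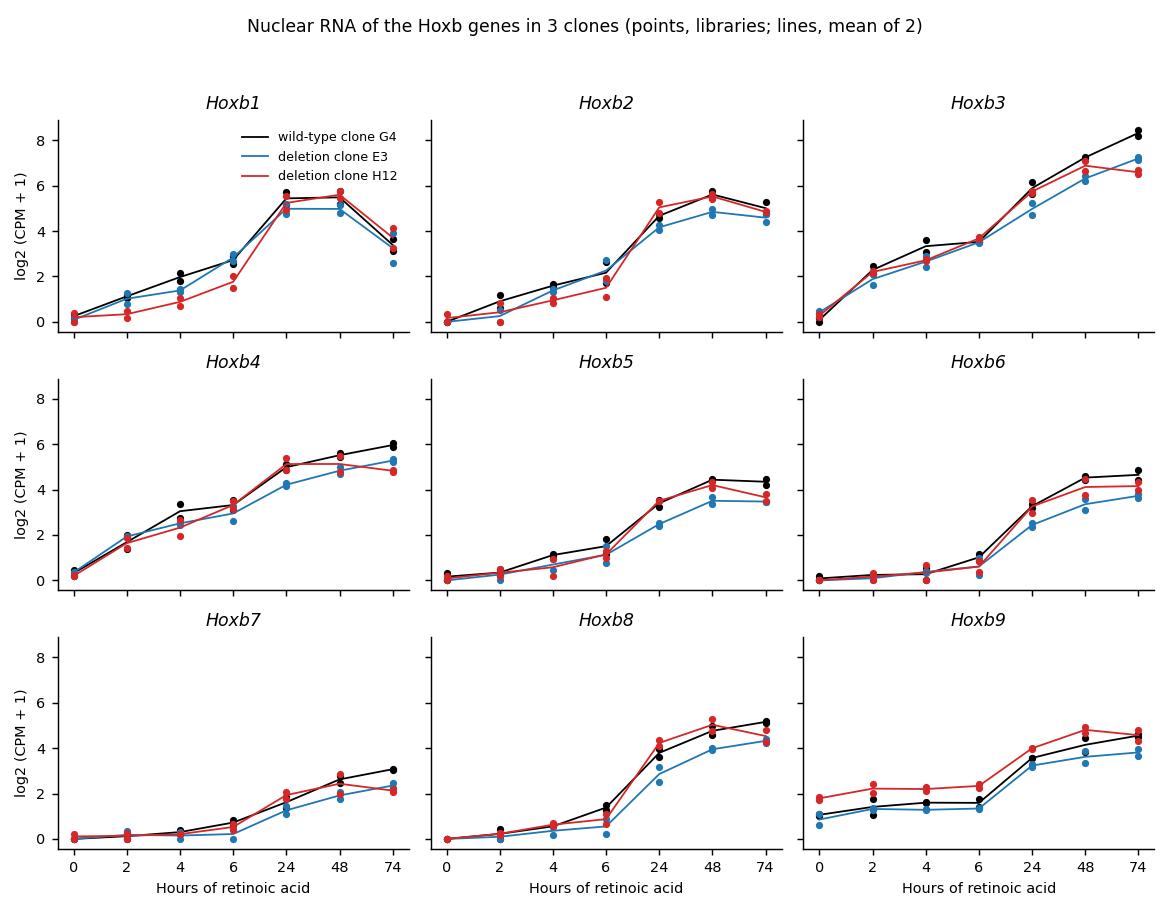
Log2 of CPM + 1 of 9 Hoxb genes in nuclear RNA of the wild-type clone (black) and deletion clones E3 and H12, with a point per library and lines through the means of 2 libraries, against hours of retinoic acid (evenly spaced). At 74 h Hoxb3 means are 321 CPM in the wild-type clone and 121 CPM over the deletion clones.

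Before RA the deletion clones already differed from the wild-type clone, 209 genes up and 473 down. Lower genes included the cytoskeletal and matrix genes Acta2 (-2.17 ± 0.41), Col1a1 (-1.64 ± 0.43), Krt18 (-1.71 ± 0.49) and Krt8 (-1.64 ± 0.48), the cadherin Cdh2 (-1.41 ± 0.27, adjusted p = 0.00178) and the neural factors Pou3f1 (-0.95 ± 0.25), Sox11 (-1.16 ± 0.21) and Neurod1 (-1.16 ± 0.26). Stag3, a meiotic cohesin gene, was higher (0.69 ± 0.20). All of these genes were called in H12 and none in E3 when each clone was set against wild type: E3 differed from the wild-type clone in 72 genes and H12 in 1903, and Acta2 was 3.91 ± 0.59 and Krt18 4.43 ± 0.67 higher in E3 than in H12. Fibroblast genes were lower, 3 of 11, with 5 in H12 and 0 in E3 (7 adjusted over the list alone; camera adjusted p = 4.17e-05, or 0.216 with an estimated correlation). The count of 682 genes was 102, 388 and 414 without wild-type library 1, E3 library 2 and H12 library 2.

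From 2 to 6 h the deletion clones had 141, 106 and 264 genes higher and 525, 508 and 627 lower. The protocadherin gene Pcdh18 was lower at 2 h (-4.06 ± 0.51, adjusted p = 6.59e-06), Meis1 at 2 h (-1.36 ± 0.24), 4 h (-1.27 ± 0.20, adjusted p = 1.98e-04) and 6 h (-0.93 ± 0.19), and Pou3f1 at 4 h (-1.45 ± 0.26) and 6 h (-1.69 ± 0.26, adjusted p = 1.08e-04). Lef1 (-0.91 ± 0.20), Pax6 (-1.15 ± 0.27) and Wnt8a (-0.98 ± 0.28) were lower at 4 h, and Nes (-1.85 ± 0.52), Junb (-1.39 ± 0.29) and Myc (-0.88 ± 0.20) at 6 h. The neuropeptide receptor gene Vipr2 was higher at 4 h (2.62 ± 0.38). Pcdh18 was called against wild type in each clone, while the other genes named here were called in H12 and not in E3. Formative and primed genes were lower in 3, 4 and 4 of 11 members (4, 5 and 6 adjusted over the list alone), with adjusted p = 0.0585, 0.0208 and 0.0515 with an estimated correlation. In H12 4, 5 and 7 of them were lower than in wild type and in E3 0 at each time. Primitive streak genes at 2 h gave 0.0358 in that test, with 1 of 9 called. For the response itself edgeR called 0 genes between deletion and wild-type clones at 2, 4, 6 and 24 h, with 207, 333, 281 and 549 at an unadjusted p under 0.05. The counts of 666, 614 and 891 called genes were 116, 104 and 68 without wild-type library 1. At 4 h they were 408 and 387, and at 6 h 448 and 466, without E3 library 2 and H12 library 2, and at 6 h 496 without wild-type library 2.

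At 24 h, 72 genes were higher and 310 lower in the deletion clones. The imprinted zinc finger gene Plagl1 stood at 39.4 ± 15.5 CPM in the wild-type clone, 2.39 ± 0.768 in E3 and 4.76 ± 0.662 in H12 (-3.56 ± 0.26, adjusted p = 1.62e-10). Meis1 (-0.87 ± 0.18, adjusted p = 0.00494), Cdh2 (-1.07 ± 0.26), Sox11 (-0.94 ± 0.20), Acta2 (-2.26 ± 0.39) and Cyp1b1 (-2.07 ± 0.25) were lower and Snhg11 higher (0.65 ± 0.15). Against wild type Plagl1 was called in each clone and the other 6 genes in H12 alone: Acta2 was -4.27 in H12 and -0.26 in E3, and Cyp1b1 -3.94 and -0.19. Fibroblast genes were lower in 5 of 11, with 5 in H12 and 0 in E3 (6 adjusted over the list alone; 4.13e-06, or 0.0717 with an estimated correlation). The count of 382 was 65 without wild-type library 1 and 220 without H12 library 1.

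At 48 h neural genes were lower in the deletion clones. The neural factors Pax6 (-1.26 ± 0.21, adjusted p = 2.17e-04), Pax3 (-1.01 ± 0.18), Zic1 (-1.56 ± 0.27) and Irx3 (-1.32 ± 0.29) were lower, 12 of 22 in that list (14 adjusted over the list alone; adjusted p = 0.0136 with an estimated correlation). So were Sox3 (-1.83 ± 0.27), Sox2 (-0.74 ± 0.18), Wnt3a (-1.96 ± 0.38), Hoxd3 (-1.55 ± 0.19, adjusted p = 6.50e-06), Hoxd4 (-1.65 ± 0.21), Hoxc4 (-0.69 ± 0.21), Plagl1 (-3.75 ± 0.20), its neighbour Hymai (-3.83 ± 0.26) and the glycine receptor gene Glra1 (-3.36 ± 0.33). Gata4 (1.71 ± 0.36), Gata6 (1.18 ± 0.22, adjusted p = 0.00106), Pdgfra (1.20 ± 0.23) and Lamc1 (0.51 ± 0.13) were higher, 6 of 21 endoderm genes (11 adjusted over the list alone; adjusted p = 0.117 with an estimated correlation), with Tbx3 (1.26 ± 0.28) and Klf5 (0.89 ± 0.23). Taken alone against the wild-type clone, H12 had 12 of the 21 endoderm genes higher and E3 had 0, while 10 and 6 of the 22 neural genes were lower. Gata4, Gata6, Pdgfra, Lamc1, Tbx3, Klf5, Zic1, Irx3 and Sox2 were called in H12 alone. 322 genes were higher and 401 lower, and the response differed in 52 genes. Without E3 library 1 the count of 723 became 1359, and without wild-type library 1, wild-type library 2 and E3 library 2 it was 86, 332 and 448.

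At 74 h, 1219 genes were higher and 1496 lower, and the response differed in 1107. Neuronal genes were lower: Dcx, which encodes doublecortin (-3.02 ± 0.31, adjusted p = 4.17e-08), Elavl4 (-1.75 ± 0.18), Tubb3 (-1.55 ± 0.19), Pax3 (-1.53 ± 0.17) and the axon guidance receptor gene Robo3 (-3.51 ± 0.28), in all 17 of 22 neural progenitor genes (adjusted p = 0.00355 with an estimated correlation). The laminin genes Lama1 (1.46 ± 0.19, adjusted p = 1.46e-06), Lamb1 (1.61 ± 0.17) and Lamc1 (1.42 ± 0.13) were higher, as was Pdgfra (1.85 ± 0.23). The extra-embryonic endoderm list had 17 of 21 genes called higher (0.00355). In H12 21 of these 21 genes were above wild type and in E3 1 of 21; Lama1 was lower in E3 than in H12 (-3.26 ± 0.22). Pou5f1 (1.71 ± 0.29), L1td1 (1.91 ± 0.30), Dppa4 (1.02 ± 0.20), Tbx3 (1.65 ± 0.29) and Klf5 (1.20 ± 0.25) were higher, in general pluripotency 7 of 13 and in naive pluripotency 6 of 16 (0.0788 and 0.162). Against wild type these were 9 and 11 in H12 but 0 and 1 in E3, so the rise is carried by H12; Pou5f1 was 2.76 in H12 and 0.66, not called, in E3. Hoxa3 (-0.70 ± 0.18), Hoxa2 (-0.86 ± 0.22), Hoxa9 (-1.23 ± 0.42), Hoxd3 (-1.78 ± 0.19, adjusted p = 4.17e-08) and Hoxd4 (-1.62 ± 0.18) were lower, 4 of 9 Hoxa and 4 of 10 Hoxc and Hoxd genes (0.32 and 0.0874). Per clone Hoxd3 and Hoxd4 were called in each, Hoxa2 and Hoxa3 in H12 alone and Hoxa9 in neither. Camera called fibroblast, 2-cell-like, apoptosis and p53 lists as higher and lost each call with an estimated correlation (0.0874, 0.116, 0.0989 and 0.0989). Hoxb neighbours had 3 of 27 higher. The count of 2715 genes was 700 without wild-type library 2 and 1708 without E3 library 2.

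The direct comparison of E3 with H12 sets the scale for differences between clones of the same genotype. E3 was higher in 1061, 1299, 1168, 979, 896, 1262 and 525 genes over the 7 times in order and lower in 661, 846, 884, 749, 849, 1281 and 705. At 0 h the contractile genes Tagln (5.88 ± 0.86) and Acta2, the cytokine gene Csf1 (4.86 ± 0.57, adjusted p = 3.65e-07) and Cdh2 (2.12 ± 0.34) were higher in E3, and Stra8 (-3.52 ± 0.56), Tbx3 (-2.19 ± 0.31, adjusted p = 1.74e-05) and Klf4 (-1.08 ± 0.28) lower. Wnt3 was higher in E3 at 2 h (3.21 ± 0.54), 4 h (3.11 ± 0.48) and 6 h (3.59 ± 0.54, adjusted p = 2.47e-05), and Stra8 lower (-2.34 ± 0.36, -2.07 ± 0.35 and -1.84 ± 0.35). At 24 h Cyp1b1 was higher (3.75 ± 0.35), Gata6 lower (-2.15 ± 0.27, adjusted p = 1.78e-06), 6 of 8 trophoblast genes higher (adjusted p = 0.00232 with an estimated correlation) and 5 of 9 Hoxa genes lower (0.0539). At 48 h Col3a1 (4.11 ± 0.44, adjusted p = 5.92e-07) and Wnt6 (3.71 ± 0.35) were higher and the endocytic receptor Cubn lower (-3.84 ± 0.45); the count of 2543 at this time was 428 without E3 library 1 and 4899 without E3 library 2. At 74 h 20 of 21 extra-embryonic endoderm genes were lower in E3 (2.19e-05), with Col4a1 at -3.03 ± 0.26, and 5 of 13 general pluripotency genes (0.0207), with Pou5f1 at -2.11 ± 0.27, adjusted p = 2.04e-06. Aldh1a2, which makes RA (2.79 ± 0.31), and the mesothelial genes Upk3b (3.36 ± 0.36) and Bnc1 (3.04 ± 0.38) were higher. Without a single library the counts fell as low as 865, 1119, 1055, 741, 802 and 467 at 0, 2, 4, 6, 24 and 74 h.

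**Figure D4:**
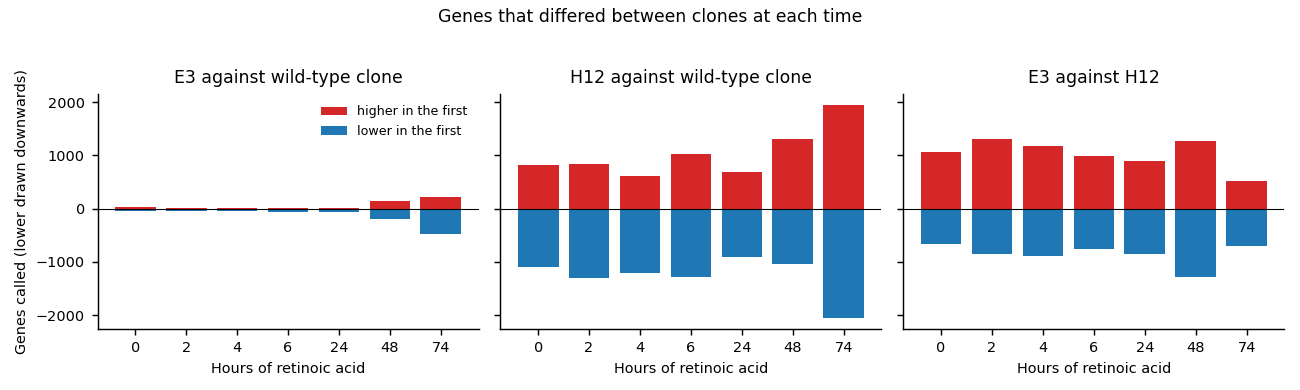
Number of genes called higher (upwards) or lower (downwards) at each time of retinoic acid for E3 against the wild-type clone, H12 against it, and E3 against H12. At 0 h E3 differs from the wild-type clone in 72 genes, H12 in 1903 and the deletion clones from each other in 1722.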

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

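Of the tests in this part, those on runs of neighbouring genes, on deleted sequence within Hoxb3, on differences between the deletion clones and on the E14 genes under the authors' scaling were chosen after the result was seen.

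Single libraries stood apart in 2 of 50 groups of 4 libraries tested, where chance gives about 1 in 20. The first is Hoxb3 in E14 cells at 2 h, where the gap of the lowest library to the next was 0.863 of the group's range. The other is Rad21 in E14 cells at 72 h, with 0.847 of the range. Neither gene was called at these times against 0 h (2.70 ± 0.81 for Hoxb3 and 0.27 ± 0.12 for Rad21), and no cause was tested.

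The response to RA differed between deletion and wild-type clones in 52 genes at 48 h (39 with a higher and 13 with a lower log2 change in the deletion clones) and in 1107 at 74 h (609 and 498), by a test of the difference itself. At 24 h 6 Hoxb genes differed between E3 and H12, which share a genotype. In SCC1-mAID cells the fitted response to RA was weaker with auxin in Ak5 (-3.28), Cyp26b1 (-3.27) and Nrip1 (-0.95), picked out by the interaction adjusted within the 214 genes that RA alone changed 2-fold. That set was chosen on the same libraries, which favours a weaker response with auxin. Over all genes their adjusted p values were 0.464, 0.464 and 0.54, and over the fixed lists 0 genes were called by edgeR, so the loss is not established.

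The first pattern weighed is the number of genes in which H12 differed from the wild-type clone before RA, 1903 against 72 for E3. Gain or loss of a whole chromosome is argued against for chromosomes with 100 or more tested genes: for H12 against the mean of E3 and the wild-type clone, the largest distance of such a chromosome's median from that of all genes was -0.08, while chromosome Y, with 9 tested genes, lay at 2.97 and stays open. Extra cells of the 5 listed types in the H12 cultures are argued against too. The highest share of a list's members called higher in H12 was 9.1%, for fibroblasts, whose median was -2.21. It was 4.8% for extra-embryonic endoderm and 0.0% for the other lists. The test counted only higher markers, so it cannot tell whether the wild-type cultures held other cells that H12 lacked. Medians were -1.10 for trophoblast, -0.63 for primitive streak and mesoderm, -0.09 for neural progenitors and 0.05 for endoderm. That possibility stays open. Runs of shifted neighbouring genes held 172 of the 1903 genes (9.0%), so direct shifts within such runs may account for part of the difference but not for most of it. The search took only runs of at least 10 genes with a running median of 0.4 or more in size. Shorter or weaker changes in copy number, and effects on genes outside the runs, would be missed and stay open. A stable difference in cell state between clones stays open and was not tested.

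The next pattern is the lower Hoxb expression in both deletion clones at 74 h. Loss of sequence from the counted span of Hoxb3 is argued against as the whole cause in both clones: the 8 other Hoxb genes, whose spans do not overlap it, were lower at 74 h by a mean of -0.70 in E3 and -0.49 in H12 (SE 0.20 each), with 2 called in each clone. For Hoxb3 itself a fixed loss is argued against in H12 by the change to 74 h, -1.92 (SE 0.30) from 6 h and -1.57 (SE 0.26) from 24 h. H12 stood at -0.74 (SE 0.27) at 4 h and -1.75 (SE 0.18) at 74 h. In E3 a fixed loss stays open: the change was -1.11 (SE 0.30) from 6 h but -0.20 (SE 0.26) from 24 h. Hoxb3 in E3 stood at -0.78 (SE 0.26) at 4 h and -0.02 (SE 0.24) at 6 h. It was at -0.93 at 24 h and at 48 h, and at -1.13 (SE 0.18) at 74 h. Of these times only 6 h goes against a fixed loss in E3. Another stage of differentiation in the deletion clones is a candidate explanation, consistent with a median of -0.70 for the Hoxa genes (-0.61 in E3 with 0 called, -0.79 in H12 with 3 called) and with lower neural genes (10 of 22 in E3, 16 of 22 in H12), but limited by the pluripotency and endoderm genes: higher in H12 were 21 of 21 extra-embryonic endoderm, 9 of 13 general and 11 of 16 naive pluripotency genes, against 1, 0 and 1 in E3. Differences between clones of the same genotype (a median of -0.94 over the Hoxb genes at 24 h) and an effect of the deletion on Hoxb genes in cis stay open as well.

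The last pattern is the weaker fitted response of Cyp26b1 and Nrip1 to RA with auxin, itself open. If the whole RA programme were weaker without cohesin, genes induced at 4 h in E14 cells would show it. Their median difference of response was -0.12 over 118 of 129 genes measured, 68 of them below zero (fry p = 0.189, camera p = 0.271 with an estimated correlation), under TMM, which centres all genes. Under the authors' scaling it was -0.38 with 91 below zero (fry p = 0.468), against -0.33 for the interaction median of all genes, so the size of a general loss stays open. Regrouping the libraries decides nothing here: with 0 genes called by the real grouping, 100 of 100 groupings must call as many, and the highest called 1208.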

How the results depend on the processing

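Of the alternatives, limma on log2 of the deposited value plus 1 was chosen after seeing the data; a change of pseudocount was not run, since whole reads were recovered. Of 242 counts under alternatives other than leaving out a library, 170 lay within 1.5 times the reported count and 72 did not. For each change below the cause was not tested. Changes of single genes printed here, 316 genes and comparisons, were called alike in 2169 tests under these alternatives, lost the call in 222 and gained it in 15, with none called in the other direction. Lost calls numbered 81 with limma on the deposited value, 53 with the authors' scaling, 35 with limma-trend and 31 with only the compared groups. With 1 library left out 1503 were called alike, 327 lost the call and 5 gained it.

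RLE factors kept all counts within 1.5 times. Keeping the authors' scaling moved total counts beyond 1.5 times in SCC1-mAID alone. RA against untreated went from 361 to 72 and auxin and RA against auxin from 370 to 47. Auxin against untreated went from 33 to 3 and auxin and RA against RA from 51 to 4. In E14 at 72 h the total went from 9010 to 8687, but genes down went from 4423 to 2800. The SCC1-mAID size factors recovered from the deposited table were 0.638 to 2.15 times median-of-ratios factors, after centring their ratio on 1. Without a filter on low counts auxin against untreated gave 153, auxin and RA against RA 87 and the interaction 3.

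DESeq2 called 140 genes at 2 h in E14 (75 in edgeR), 186 for auxin against untreated, 96 for auxin and RA against RA and 5 for the interaction. limma-trend called fewer early E14 genes, 43, 164 and 321 at 2, 4 and 6 h (75, 368 and 597 in edgeR), with 44 transient genes in place of 79, 2 Hoxb calls in place of 7 and 1 gene in the interaction. limma on the deposited value called 40, 134 and 326 at these times, 32 transient genes, 3 Hoxb genes, and 74, 50, 3 and 5 genes in the 4 SCC1-mAID contrasts in the order above.

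With the replicate number as a block, 128 genes were called at 2 h in E14, 98 for auxin against untreated, and 1039 and 1366 between deletion and wild-type clones at 0 and 6 h (682 and 891 without it). Across genes, libraries of the same number correlated above 0.1 in 28 of 67 pairs in E14, 10 of 18 in SCC1-mAID and 180 of 420 in the clones, so the numbers do not pair the libraries throughout. For auxin against untreated r was 0.16, 0.20 and -0.01.

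A fit of only the compared groups called 762 genes for RA against untreated, 144 for auxin and RA against auxin and 4 for auxin against untreated. With calls limited to 2-fold, which can only lower a count, E14 had 48, 192, 310, 1710, 4142 and 4747 genes over the 6 times. SCC1-mAID had 214, 197 and 31 for RA against untreated, auxin and RA against auxin, and auxin and RA against RA. Deletion against wild-type clones had 272, 304, 256, 317, 127, 233 and 935 over the 7 times, E3 against H12 1008, 1200, 1184, 1001, 870, 970 and 662, and the Hoxb genes 1. A 1.5-fold limit gave 124 transient genes. Lists called by camera numbered 155 with the preset correlation and 42 with an estimated correlation.

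Each clone alone gave very different counts against the wild-type clone. E3 gave 72, 54, 53, 81, 68, 343 and 695 genes over the 7 times, and H12 gave 1903, 2139, 1821, 2313, 1579 and 2335 up to 48 h, where both clones gave 682, 666, 614, 891, 382, 723 and 2715.

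Leaving out a library of a pair leaves a lone library, assumed to vary as the other groups do. In E14 the 0 h libraries set the counts: without replicate 3 and without replicate 4 these were 18 and 20 at 2 h, 70 and 83 at 4 h, 148 and 172 at 6 h, 2244 and 1916 at 24 h, and 28 and 29 transient genes. Ranges over all libraries left out were 18 to 75, 70 to 357, 148 to 551, 1916 to 3976 and, for transient genes, 28 to 86; at 48 h (6382 to 8223) and 72 h (7170 to 8840) all counts were within 1.5 times.

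In SCC1-mAID the ranges were 212 to 250 for RA against untreated (221, 223 and 212 without untreated libraries 1, 2 and 3), 215 to 828 for auxin and RA against auxin, 4 to 68 for auxin against untreated, 8 to 63 for auxin and RA against RA, and 0 to 0 for the interaction. For auxin and RA against auxin the counts without auxin and RA libraries 1, 2 and 3 were 216, 828 and 225, and without auxin libraries 1, 2 and 3 719, 215 and 223. For auxin against untreated they were 4, 6 and 9 without untreated libraries 1, 2 and 3, and 19 and 68 without auxin libraries 2 and 3. For auxin and RA against RA they were 24, 30 and 20 without RA libraries 1, 2 and 3, and 8 without auxin and RA library 1.

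Between deletion and wild-type clones the ranges over 0, 2, 4, 6, 24, 48 and 74 h were 102 to 757, 116 to 608, 104 to 565, 68 to 625, 65 to 369, 86 to 1359 and 700 to 2737. The lowest came without wild-type library 1 up to 48 h and without wild-type library 2 at 74 h. Counts were also moved by E3 library 2 at 0, 4, 6, 48 and 74 h (388, 408, 448, 448 and 1708), H12 library 2 at 0, 4 and 6 h (414, 387 and 466), H12 library 1 at 24 h (220), wild-type library 2 at 6 and 48 h (496 and 332) and E3 library 1 at 48 h (1359). For E3 against H12 the ranges were 865 to 1268, 1119 to 1732, 1055 to 1420, 741 to 1110, 802 to 1073, 428 to 4899 and 467 to 842. At 48 h E3 library 1 and E3 library 2 gave 428 and 4899, and H12 library 1 gave 850. At 0 h E3 library 1 and H12 libraries 1 and 2 gave 967, 1015 and 865, at 2 h E3 library 1 and H12 library 2 gave 1200 and 1119, and at 4 h E3 library 1 and H12 libraries 1 and 2 gave 1055, 1120 and 1153. At 6 h E3 libraries 1 and 2 and H12 libraries 1 and 2 gave 741, 1110, 1090 and 800, at 24 h 1073, 990, 802 and 875, and at 74 h E3 library 1 and H12 library 1 gave 467 and 762. Hoxb calls ranged from 3 to 11: 3 without wild-type library 1, wild-type library 2 or H12 library 1 at 74 h, and 11 without H12 library 2 at 48 h.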

Other observations

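Of the tests in this part, those on imprinted genes, on runs of neighbouring genes and on reads from long genes were chosen after the data were seen, and the genes in the next paragraph were picked after their values were seen.

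The Y-linked genes Uty and Zfy1 differed between the clones, with the highest mean in H12 and the lowest in E3 at each time. At 0 h Uty stood at 91.5 ± 7.78 CPM in the wild-type clone, 33.9 ± 5.76 in E3 and 440 ± 33.6 in H12 (SD, n = 2 each). Zfy1 stood at 3.46 ± 0.533, 1.39 ± 1.01 and 84.6 ± 3.29 CPM, and E3 lay below H12 at 0 h (-5.92 ± 0.30, adjusted p = 6.09e-15) and at 74 h (-5.64 ± 0.33). The X-linked gene Xlr4a was lower in E3 than in H12 as well (-4.40 ± 0.81 at 0 h). No explanation was tested.

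A larger share of imprinted genes than of all genes was called between clones, on a list chosen after the calls were seen and without a test of the difference. Of 42 measured genes of a list of 44, 14.3% were called between E3 and the wild-type clone at 0 h, against 0.5% of all genes. Between H12 and the wild-type clone 38.1% were called, where 1903 of 15923 genes were called in all. At 74 h the shares were 14.3% and 38.1%, against 4.4% and 25.1%. The comparison uses the same wild-type libraries for both clones, and whether imprints changed was not tested.

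Runs of neighbouring genes were shifted in each deletion clone, by the mean over all times. E3 had 2 runs against the wild-type clone, on chromosome 11 from 58307069 to 62223013 (61 genes, median -0.52) and on chromosome 7 from 125444620 to 127925762 (69 genes, -0.63). H12 had 10, with the lowest median on chromosome 17 from 78653964 to 88490533 (49 genes, -0.96), and overlapping runs on chromosome 7 (72 genes, -0.64) and chromosome 11 (58 genes, -0.48). After shuffling gene positions, 0 of 100 orders gave a run for E3 and 1 of 100 for H12. Shuffling also separates neighbours that are regulated together or share reads, so it cannot tell copy number from these. The H12 runs include that from Pcdha1 to Hdac3 on chromosome 18 (41 genes, -0.60). Another, from Hist1h4j to Hist1h4i on chromosome 13, had medians from -0.67 to 0.01 over the times. Runs shared by both clones are measured against the same wild-type libraries, so a gain in the wild-type clone and a loss in both others cannot be told apart. The E3 runs held 20 of the 72 genes called at 0 h (27.8%), where 1.0% of tested genes lie in them. At 2, 4, 6 and 24 h the share was 35.2, 35.8, 39.5 and 51.5%, and at 48 and 74 h it was 14.9 and 9.2%. The runs were picked from the same differences between E3 and wild type that give the calls, which raises these shares. They are thus no test of copy number. Direct shifts within these runs could explain at most part of the E3 calls, up to these shares. The values leave the rest open.

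Cyp1a1 and Cyp1b1 rose with auxin, and a candidate explanation is activation of the aryl hydrocarbon receptor by auxin. The other 6 measured targets had a median of 0.20, with Ahrr at 2.16 ± 0.56 (adjusted p = 0.116), Tiparp at 0.52 ± 0.25 and Nqo1 at 0.14 ± 0.18. None of these 6 was called, so the explanation stays open. Cells without the tag given auxin would separate it from loss of cohesin.

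Other splits of the SCC1-mAID libraries were tried for each treatment contrast. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. RA against untreated called 361 genes, in 1 of 10 splits as many, and the highest other split 0; auxin against untreated called 33 (1 of 10, highest other 0), and auxin with RA against RA called 51 (1 of 10, highest other 0). For auxin with RA against auxin the real split called 370 and another called 3417, so 2 of 10 reached the real count, which points to a structure of these samples. That split set auxin and RA libraries 1 and 3 and auxin library 1 against the other 3. These are the libraries with the smaller share of reads from genes over 100000 bp, at 14.5%, 13.0% and 13.2% against 17.3%, 16.6% and 17.4%. That grouping cuts across treatment, and its source was not tested.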
